A study of Caenorhabditis elegans with 2 samples.

How the data were processed

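ChIP-seq regions of eGFP-LSY-2 in L2 larvae were analysed for 1 group of 2 biological replicates, numbered as in the labels; p-values across regions or genes describe these libraries. The authors called regions for each replicate and for both replicates together on alignments to ce10 and to ce11 against a control alignment, per the deposited lists of files, and thresholded them by IDR. The aligner, the caller and their versions are not given in the sources used here. The control library itself was not analysed here. The deposited signal value of each region is the caller's own, relative to the control in a way that is not given in the sources used here, and is not scaled between replicates. It was used to rank and describe regions, to compare regions and gene groups within a list, and to correlate the replicates across regions; the ratio of signal between replicates depends on their scale, which was not matched. The deposited −log10 q-value was at its maximum of 3.63 for 97.6% of the thresholded regions, so it was not used for ranking. The p-value column of the deposited lists held no values.

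The ce11 lists are the main ones and ce10 lists an alternative; no coordinate was moved between builds. All 2182 thresholded regions on ce11 were the 2182 regions of highest signal in the list for both replicates together. One pair of them shares its start and end and differs in summit. Genes were those of Ensembl release 115 on WBcel235, the assembly of ce11, and sequence was taken from the RefSeq copy of that assembly. The promoter window of a gene ran from 1000 bp upstream to 200 bp downstream of its annotated 5′ end, and a summit within it was assigned to every such gene, so neighbouring genes can share a summit. Mitochondrial genes were left out.

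Chance levels for positions came from 1000 circular shifts of the summits along each chromosome by at least 50 kb, which keep their spacing. Gene lists were tested with Fisher's exact test against all other nuclear protein-coding genes, with Benjamini-Hochberg adjustment over the 28 lists. Noncoding RNA genes were tested by distance, within 200 bp, in 6 classes. Every 6-mer, together with its reverse complement, was counted within 50 bp of the summits and in windows of the same width centred 300 bp to each side, with Fisher's exact test adjusted over 6-mers. Replicates were compared by the overlap, of at least 1 bp, of their 2182 regions of highest signal, and by the signal of each replicate's strongest region with a summit inside a thresholded region. Regions at lsy-2 and unc-119 were compared with 1000 random 40 kb windows that held at least 1 region. Intervals of shares are Wilson intervals at 95%; depth is unknown, so they cover only the number of regions or genes.

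Lists, tests, windows and the rule for named genes were fixed before the data were examined. The text names the genes whose promoter window holds one of the 20 strongest summits, up to 4 members with a summit of each list called as having more (up to 2 where fewer), every heterochronic, Hox and ASE neuron member with a summit, lsy-2 and unc-119. Alternatives were the ce10 lists, the upper 50% of regions, each replicate's own top 2182 regions in place of the thresholded list (leaving out the other replicate), other promoter windows, the nearest 5′ end within 5 kb, other overlap criteria, list lengths and distances, shuffled positions, other control windows, 5-mers and 7-mers, and other backgrounds for the lists. Those added after the data were seen are the 200 regions of highest signal for 6-mers, the lower 50% of regions for lists and for the signal of replicates, a background of genes with a symbol other than a sequence name, random windows with as many regions as the lsy-2 window, and lists without 6 members of other function. Several lists were drawn by the letters of gene symbols, so such members can remain in others. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used. The statistics were tested on simulated data with planted promoter summits, lists, 6-mers and overlaps. All 9 checks passed, with 0 of 200 random lists called among 2400 simulated genes. Apart from what was planted, the list and 6-mer checks drew genes with a summit and bases at random. They held no summits shared by neighbouring genes and no uneven base composition, so they do not give error rates for the real data.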

Results

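Binding sites of LSY-2, a C2H2 zinc finger transcription factor needed for the left/right asymmetry of the ASE taste neurons of Caenorhabditis elegans, were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq). The worms were whole L2 larvae of mixed sex of strain OP240, which carries an integrated transgene (wgIs240) expressing LSY-2 fused to eGFP in an unc-119(ed3) background. The data form 1 group with 2 biological replicates, and no comparison between conditions is part of the design. For each replicate the authors listed 30000 regions, peaks and background together, and from both replicates they derived a list of regions that passed a threshold on the irreproducible discovery rate (IDR), a measure of how well the ranks of regions agree between replicates. Read counts are not given in these lists, so the depth is unknown. Coordinates are those of ce11, and the signal of a region is the authors' value.

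The tagged gene itself, lsy-2 (WBGene00003087, chromosome X, 2089704 to 2093256), had no thresholded summit in its promoter window. Within 20 kb to each side of lsy-2, replicate 1 had 2 listed regions and replicate 2 had 1, where random 40 kb windows held a median of 11. The median signal of these regions was 1.52 ± 0.0676 times the genome median (SD, n = 2), and it lay at percentile 98.6 of 1000 random windows in replicate 1 and 99.2 in replicate 2. The ratio rests on those 3 regions. Against windows that held as many regions as the lsy-2 window, a test added after the data were seen, the percentiles were 91.6 and 93.6 (permutation p = 0.17 and 0.13). With 40 kb to each side the replicates went apart, at 1.21 times the genome median in replicate 1 and 0.781 in replicate 2, with a mean of 0.996. At unc-119 (chromosome III, 10902641 to 10908935), whose rescuing copy is used to select such transgenes, the ratios were 0.951 and 1.02 in the replicates, at percentiles 40 and 57.9.

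The 20 strongest eGFP-LSY-2 regions all had their summits upstream of protein-coding genes, and several of these genes encode ribosomal proteins. The region of highest signal (6690; 4092 in replicate 1 and 2620 in replicate 2) covered chromosome IV, 4749808 to 4750328, and its end reached into Y17G9B.5, which starts at 4750240. Its summit, at 4750065, lay between the genes, 287 bp upstream of the 5′ end of rpl-20, a large ribosomal subunit gene, and 175 bp upstream of that of Y17G9B.5. The next were upstream of rpl-3 (signal 6665; chromosome III, 3867272 to 3867811) and of cox-5A, a cytochrome c oxidase subunit gene (signal 5786; chromosome III, 12904957 to 12905439). Among the 20 regions of highest signal, others lay in the promoter windows of the ribosomal protein genes rps-1, rpl-15 and rps-20, of the ubiquitin and ribosomal protein fusion gene ubq-2, of the translation elongation factor gene eef-2, of the chaperonin subunit genes cct-8 and cct-1, of the ATP synthase gene atp-1 and of the adenine nucleotide translocator gene ant-1.1. The chromatin genes lin-53 (signal 4074) and lin-9 (signal 3225), both encoding subunits of the DREAM complex, and the histone acetyltransferase gene cbp-1 (signal 2019) were also among them. The other genes whose windows held one of these 20 summits were syx-5, F55A11.1, ifet-1, K11H12.8, Y55F3AR.2, cap-2, gmps-1, Y25C1A.8, nra-2, mig-5, serp-1.1, ekl-4, cup-14, ndub-8, frg-1, clsp-1, mcrs-1, T27E9.2 and abcf-2. All 20 summits lay within 1 kb upstream of an annotated 5′ end and outside exons and introns of protein-coding genes, and together these regions held 20% of the summed signal of the thresholded list.

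The thresholded list held 2182 regions with a median width of 364 bp and a median signal of 83.4 (45.8 to 6690). Among them, 1676 (76.8%) overlapped one of the 2182 regions of highest signal in both replicates. Of the 2182 regions of highest signal in replicate 1, 1692 overlapped one of the 2182 highest in replicate 2 (77.5%, 95% Wilson interval 75.8 to 79.3%), against a mean of 1.55% and a highest value of 2.38% over 1000 circular shifts of the regions (one-sided permutation p = 0.001, the smallest these shifts can give). Across the 2154 thresholded regions with a listed summit in both replicates, Pearson's r of log10 signal was 0.890 and Spearman's rho 0.765 (95% bootstrap interval 0.742 to 0.788). This is a correlation across regions, which are not independent replicates. The signal was a median 1.43 times higher in replicate 1, and the SD of the log2 ratio between replicates was 0.55. At the top of the list the order was nearly the same in both replicates: rpl-20 ranked 1 and 2, rpl-3 ranked 2 and 1 and cox-5A ranked 3 and 3 in replicates 1 and 2. In the lower 50% of the thresholded regions by signal, an alternative added after the data were seen, rho was -0.10, among regions that were chosen on the signal of both replicates together.

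**Figure D1:**
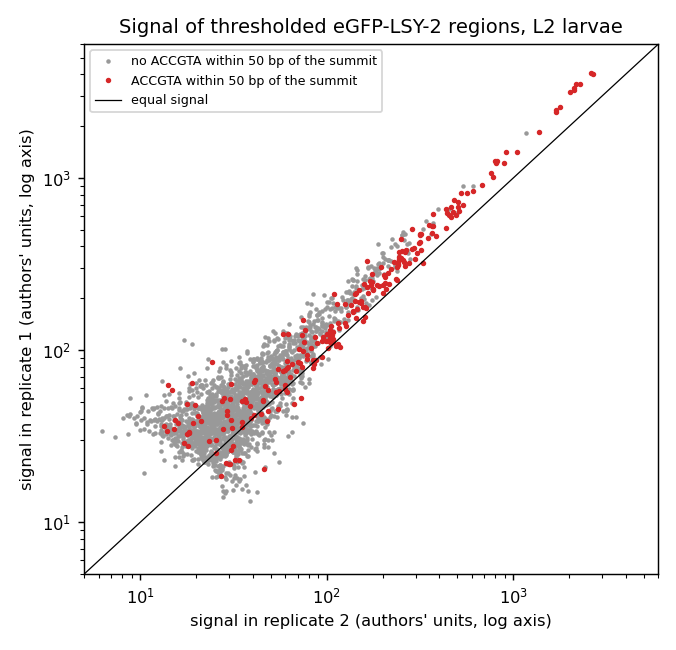
Signal of each thresholded region in replicate 2 (x axis) and replicate 1 (y axis), in the authors' units on log axes; each point is 1 of the 2154 regions with a listed summit in both replicates, red where ACCGTA lies within 50 bp of the summit. Points lie mostly above the line of equal signal, by a median ratio of 1.43, and ACCGTA was at 84.0% of the 50 regions of highest signal.

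Summits lay mainly just upstream of protein-coding genes. Of the 2182 summits, 1411 (64.7%, 95% Wilson interval 62.6 to 66.6%) were in a promoter window, from 1000 bp upstream to 200 bp downstream of an annotated 5′ end, against a mean of 21.1% and a highest value of 24.2% over 1000 circular shifts (two-sided permutation p = 0.002, the smallest these shifts can give). Coding exons held 28 summits (1.28%, 24.8% by chance), introns 408 (18.7%, 34.3% by chance) and UTRs 102 (4.67%, 4.97% by chance); of these only the UTR share did not differ from the shifts (adjusted permutation p = 0.561; 0.0025 for the others). Of the summits in promoter windows, 529 (37.5%) lay in windows of genes on both strands, such as the pair rpl-20 and Y17G9B.5, against 10.2% by chance (highest 14.3%). The median summit was 163 bp upstream of the nearest 5′ end. Because many C. elegans transcripts are trans-spliced, an annotated 5′ end is often not the transcription start. In all, 1968 of the 19973 nuclear protein-coding genes (9.85%) had a summit in their window.

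**Figure D2:**
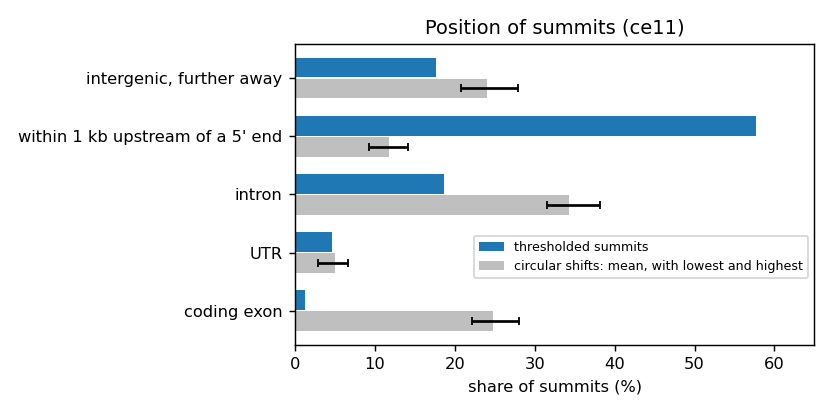
Share of the 2182 summits (x axis, %) in each kind of position (y axis) for the thresholded list (blue) and for 1000 circular shifts (grey, mean with lowest and highest value). Positions within 1 kb upstream of a 5′ end held 57.7% of summits against 11.8% by chance.

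The X chromosome had fewer genes with a summit than the pooled autosomes, while chromosome V was as low. A summit lay in the promoter window of 150 of 2731 X-linked genes (5.49%) and of 1818 of 17242 autosomal genes (10.5%), an odds ratio of 0.493 (two-sided Fisher's exact p = 1.97e-18). On chromosome V the share was 5.61% (280 of 4994 genes), and on the other autosomes it was 9.42% to 16.4%. X-linked summits were also less often in promoter windows than autosomal ones (141 of 299, 47.2%, against 1270 of 1883, 67.4%; odds ratio 0.431, Fisher's exact p = 3.04e-11, a test added after the data were seen). When each summit was given to the nearest 5′ end within 5 kb instead, the X chromosome no longer differed (odds ratio 0.937, Fisher's exact p = 0.38). Regions were densest on chromosomes III (33.2 per Mb) and I (29.9 per Mb) and sparsest on V (13.3 per Mb), with 16.9 per Mb on X. With each chromosome split into 3 equal parts, the central part of III held 41.6 regions per Mb and its outer parts 28.9, whereas the central part of X held 13.2 and its outer parts 18.7.

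Genes of basic cellular machinery had LSY-2 summits far more often than other genes. Of 81 ribosomal protein genes, 67 (82.7%) had a summit in the promoter window, against 9.56% of all other protein-coding genes (odds ratio 45.3, exact test, adjusted p = 1.71e-52), led by rpl-20, rpl-3, rps-1 and rpl-15. So did 21 of 33 proteasome genes (odds ratio 16.2, exact test, adjusted p = 5.12e-13; 8.91 without replicate 1), among them rpn-5 (signal 952), pas-4 (631), rpn-3 (424) and rpn-11 (325), and 26 of 47 genes on the list for the mitochondrial respiratory chain (odds ratio 11.5, adjusted p = 8.71e-14), among them cox-5A, atp-1, cox-5B (signal 1221) and the assembly factor gene cox-14 (signal 674). That list was drawn by the letters of symbols and took in lpd-2, lpd-3, lpd-6, lpd-7 and lpd-9, all with a summit, which are not known as respiratory chain genes. They were singled out after their values were seen. Without them 21 of 42 genes had a summit (odds ratio 9.24, exact test, adjusted p = 3.23e-10). The median signal at the 67 ribosomal protein promoters was 300.1, 3.09 times that of the other 1901 genes with a summit (permutation p = 2e-05, the smallest that 100000 permutations can give). With each summit given only to the nearest 5′ end within 5 kb, 42 of the 81 ribosomal protein genes had one (odds ratio 10.5), and the odds ratio was 7.14 for the respiratory chain list. Among genes with 500 bp upstream free of other protein-coding genes, it was 88.0 for ribosomal protein, 58.05 for proteasome and 29.02 for respiratory chain genes. All p-values of lists are two-sided Fisher's exact tests adjusted by Benjamini-Hochberg over the 28 lists fixed in advance.

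The smaller lists of synMuv B and DREAM, pan-neuronal and heterochronic genes also had summits more often than other genes. Other lists of developmental regulators or neuronal genes did not, as given below. Of 18 synMuv B and DREAM genes, which repress germline and vulval genes in somatic cells, 7 had a summit (odds ratio 5.84, exact test, adjusted p = 0.00271), with lin-53, lin-9, lin-54 (signal 548) and the E2F gene efl-1 (signal 197) the strongest. The summit assigned to lin-54 lay 367 bp upstream of it but 26 bp upstream of a ribosomal protein gene. Of 20 pan-neuronal genes, 7 had a summit (odds ratio 4.94, exact test, adjusted p = 0.00469), including syd-2 (signal 90.2), snb-1, which encodes synaptobrevin (87.6), ric-19 (74.3) and rgef-1 (65.03). Of 11 heterochronic genes, which time larval development, 4 had one (odds ratio 5.24, exact test, adjusted p = 0.0328): lin-46 (signal 90.3), lin-66 (68.4), lin-28 (61.97) and lin-14 (56.5). The last calls rested on weak regions: in exact tests the pan-neuronal list was not called from replicate 2 alone (odds ratio 3.14, adjusted p = 0.0697) and the heterochronic list not from replicate 1 alone (adjusted p = 0.152). Only 2 of the 7 pan-neuronal and 1 of the 4 heterochronic genes had a summit in the upper 50% of regions, where neither list was called. The summit assigned to lin-46 lay more than 500 bp upstream of it but 20 bp upstream of the nearest 5′ end, that of another gene. No listed summit of replicate 1 lay inside the thresholded region at lin-66, although the promoter window of lin-66 held a region ranked 1811 in replicate 1. The region at lin-14 ranked 2509 in replicate 1, outside its top 2182. With a promoter window of 500 bp upstream to 100 bp downstream the heterochronic list was not called either (exact test, adjusted p = 0.328). With the nearest 5′ end within 5 kb the odds ratio was 14.4 for pan-neuronal, 11.5 for heterochronic and 3.68 for synMuv B and DREAM genes.

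**Figure D3:**
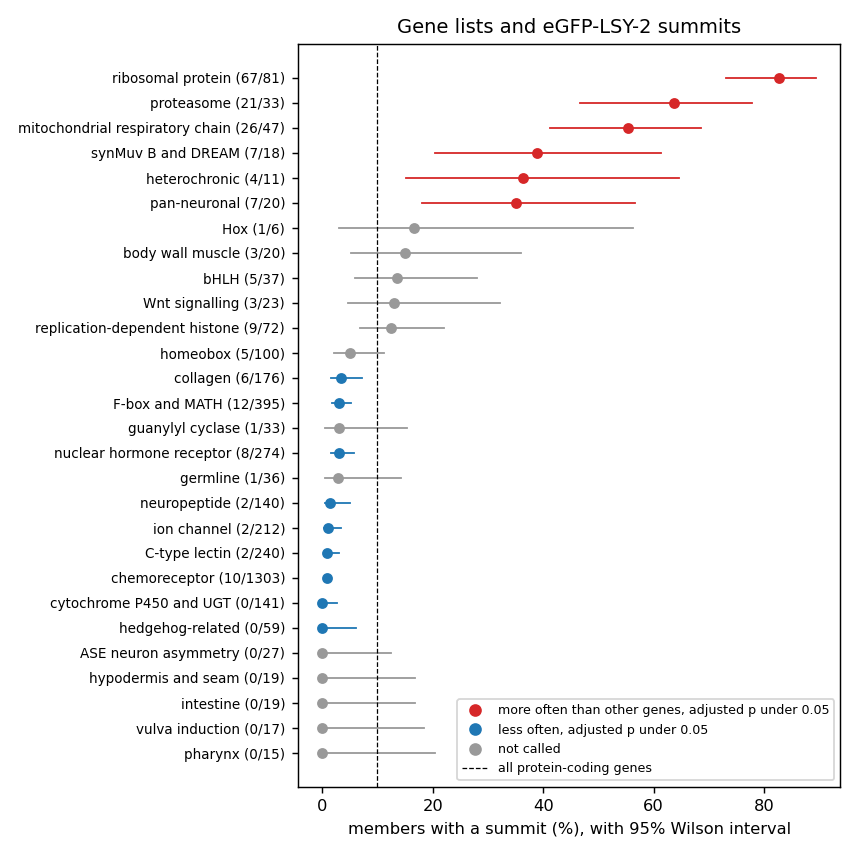
Share of the members of each of 28 gene lists (y axis, members with a summit and all members) with a thresholded summit in the promoter window (x axis, %), with 95% Wilson intervals; red lists had summits more often than other genes, blue lists less often and grey lists were not called. Ribosomal protein genes stand at 82.7%, and the dashed line marks all protein-coding genes at 9.85%.

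Large families of receptors, detoxification enzymes and secreted proteins had fewer summits than other genes. Chemoreceptor genes had a summit at 10 of 1303 members (0.768%; odds ratio 0.066, exact test, adjusted p = 7.29e-45), the strongest at srh-16 (signal 317) and sri-5 (299.5). One of the 10, stl-1, encodes a stomatin-like protein and was on the list by the letters of its symbol. Without it, a choice made after the values were seen, 9 of 1302 had a summit (odds ratio 0.0594, exact test, adjusted p = 5.87e-46). In exact tests the same direction held for nuclear hormone receptors (8 of 274, odds ratio 0.272, adjusted p = 4.45e-05; nhr-47 and nhr-142), collagens (6 of 176, 0.321, adjusted p = 0.00469; col-38 and col-71), neuropeptides (2 of 140, 0.132, adjusted p = 0.00042; nlp-4 and ins-39) and ion channels (2 of 212, 0.0862, adjusted p = 7.26e-07; clh-5 and glr-6). In exact tests it also held for F-box and MATH genes (12 of 395, 0.282, adjusted p = 9.07e-07; bath-42 and fbxb-85), C-type lectins (2 of 240, 0.0759, adjusted p = 5.73e-08; clec-126 and clec-104), cytochrome P450 and UGT genes (0 of 141, adjusted p = 2.2e-06) and hedgehog-related genes (0 of 59, adjusted p = 0.00727). Without replicate 1 the odds ratio was 0.0337 for chemoreceptors and 0.0388 for C-type lectins, and without replicate 2 it was 0.134 for ion channels. Set against circular shifts of the summits instead of against other genes, the chemoreceptor list alone of these 9 was called (10 summits against a mean of 24.9, permutation test, adjusted p = 0.00699). For the other 8 the adjusted p against shifts was 0.247 or more. Of these, 3 had more summits than the mean of the shifts: nuclear hormone receptors (1.45 times), collagens (1.42 times) and F-box and MATH genes (1.14 times). Because the shifts put 21.1% of summits in promoter windows, against 64.7% observed, these ratios do not mean more summits than at other genes.

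The genes of the ASE neuron pathway in which LSY-2 is known to act had no thresholded summit in their windows: 0 of the 27 protein-coding members, among them cog-1, die-1, che-1 and lsy-2 (exact test, adjusted p = 0.183). By this test the list did not differ from other genes, 9.87% of which had a summit. The chromatin came from whole larvae, not from ASE neurons alone. The microRNA genes lsy-6, lin-4, mir-48, mir-84 and mir-241 had no thresholded summit in their windows either. The heterochronic list also names let-7, for which no value is given here. Of the 6 Hox genes, ceh-13 had a summit (signal 66.7; rank 2893 in replicate 2, outside its top 2182), and the list was not called (exact test, adjusted p = 0.48). By exact test no call was made for germline genes (1 of 36, adjusted p = 0.341), body wall muscle (3 of 20, 0.474), pharynx (0 of 15, 0.474), intestine (0 of 19, 0.341), hypodermis and seam (0 of 19, 0.341), Wnt signalling (3 of 23, 0.49), vulva induction (0 of 17, 0.474), guanylyl cyclases (1 of 33, 0.341), homeobox genes (5 of 100, 0.21) or bHLH genes (5 of 37, 0.474). Nor was one made for the list of replication-dependent histones (9 of 72, exact test, adjusted p = 0.474). That list took in every gene with a numbered his symbol, and some of its members with a summit share it with another member. Against circular shifts the bHLH and histone lists had more summits than chance (permutation tests, adjusted p = 0.0187 and 0.00699). The shifts put 21.1% of summits in promoter windows, against 64.7% observed. This is thus no excess over other genes, against which neither list was called. By exact test the homeobox list had fewer summits than other genes in the narrower promoter window (odds ratio 0.23, adjusted p = 0.0311), and the Hox list had more with the nearest 5′ end within 5 kb (odds ratio 9.56, adjusted p = 0.0294).

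Summits were also frequent beside small noncoding RNA genes. Within 200 bp of a tRNA gene lay 113 summits (5.18% of all), 20.6 times the mean of the circular shifts, and within 200 bp of a snoRNA gene 75 summits (17.5 times). SL RNA genes, whose transcripts supply the spliced leader, had 12 summits (37 times) and snRNA genes 15 (13.7 times); for these 4 classes the adjusted permutation p was 0.003, the smallest that 1000 shifts could give here. For miRNA genes the 7 summits were 2.72 times the shifts (permutation test, adjusted p = 0.0432), a call that ended when replicate 2 was left out (2.36 times, adjusted p = 0.0911). The shifts put 21.1% of summits in promoter windows, against 64.7% observed, and 24.8% in coding exons, against 1.28%. The miRNA ratio thus cannot be told apart from a general preference for sequence upstream of genes. No summit lay near the 20 annotated nuclear rRNA genes, against a mean of 0.0178% of summits by chance (permutation test, adjusted p = 1).

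The sequence at the summits was rich in 6-mers with CG and in GA repeats. ACGCGC was within 50 bp of 15.9% of summits and in 1.42% of windows 300 bp to each side (odds ratio 13, exact test, adjusted p = 1.03e-106), GACGCA was at 388 (17.8% against 2.36%) and GAGAGA at 554 (25.4% against 6.76%). In all, 392 of 2080 6-mers were at least 2 times more frequent by odds ratio at adjusted p under 0.05. With windows at promoters without a region as the control, ACGCGC was again first (15.9% against 1.94%). With 100 bp to each side of the summit it ranked 4 (odds ratio 8.38), ACGCAG was first and 262 6-mers passed. A further 6-mer, ACCGTA, was at 237 summits (10.9% against 2.8%, exact test, adjusted p = 4.8e-37) and ranked 50 by p in the whole list, or 79 with 100 bp to each side (odds ratio 2.69). It ranked 6 in the upper 50% of regions and 1 among the 200 regions of highest signal, a set chosen after the data were seen. There it was at 105 summits (52.5%) and in 5 of 400 flanking windows (1.25%). Its share fell from 84.0% at ranks 1 to 50 (95% Wilson interval 71.5 to 91.7%) to 4.0% at ranks 801 to 1600 (2.85 to 5.59%), where flanking windows had 3.19%, while GACGCA was at 20% and 17.2% of these summits.

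**Figure D4:**
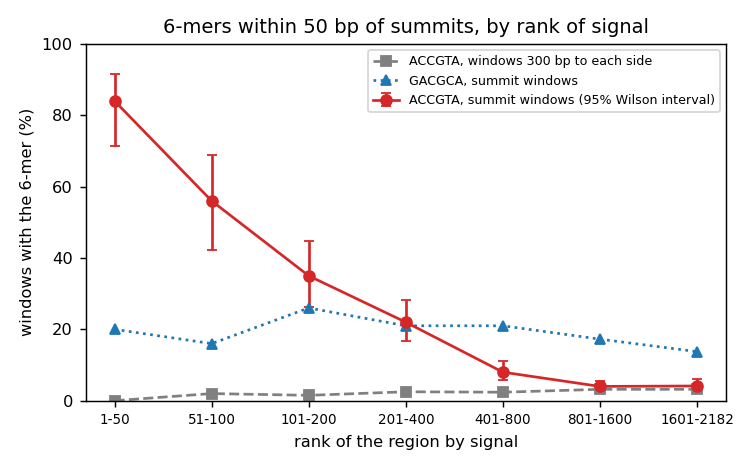
Share of summit windows with ACCGTA (red, 95% Wilson interval) or GACGCA (blue) and of flanking windows with ACCGTA (grey) on the y axis (%), by rank of the region's signal on the x axis. ACCGTA goes from 84.0% at ranks 1 to 50 to 4.12% at ranks 1601 to 2182, near the flanks, which hold 3.18% there.

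Of the 20 regions of highest signal, 19 had ACCGTA within 50 bp of the summit. The exception was the region between cct-1 and mig-5. Upstream of rpl-20 the 6-mer stood in GTGTTCTATTACCGTATCCTTCATAC (chromosome IV, 4750066 to 4750091, plus strand), with its centre 14 bp from the summit. Upstream of rpl-3 it stood in ACACGCTTTTACCGTAGCTGTGGCGG (chromosome III, 3867557 to 3867582, minus strand), and upstream of cox-5A in ACACGCTTTTACCGTAGTCCGATCAA (chromosome III, 12905165 to 12905190, plus strand). All 3 lay outside the exons and introns of protein-coding genes. In the 200 regions of highest signal, 108 of the 135 occurrences within 400 bp of a summit lay within 50 bp of it.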

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

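Regions that the authors listed but that did not pass the IDR threshold were outside the main results, and those just below it also lay preferentially at promoters. This test was chosen after the thresholded list had been examined. In the list for both replicates together, 37.7% of the summits ranked 2183 to 4364 by signal were in promoter windows, against a mean of 21.1% and a highest value of 24.6% over 1000 circular shifts (permutation p = 0.002). For the last 2182 regions of that list the share was 21.2%, with a chance mean of 21.1%. Between the replicates, 21.0% of the regions ranked 2183 to 4364 in replicate 1 overlapped one of the same ranks in replicate 2, against 1.63% by chance.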

How the results depend on the processing

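Depth is unknown and limits what the weak regions can show. Alternatives added after the data were seen are the lower 50% of regions, genes with a symbol, lists without members of other function (all 15 calls kept), windows with as many regions for lsy-2, and the 200 strongest regions. Promoter share, replicate overlap and the 5 noncoding classes counted kept their direction and call under every alternative run, except miRNA genes without replicate 2. Taking the top regions of the list for both replicates gave the same regions as the thresholded list, so it had no value of its own, and 10 kb to each side of lsy-2 gave no mean, as replicate 1 had no region there; replicate 2 was at 1.47, percentile 95.6 (permutation p = 0.0899). By construction the upper 50% of regions held 1091, and 93 5-mers and 1493 7-mers passed against 392 6-mers, as 512 and 8192 were tested. The rank correlation of signal between the replicates rose to 0.831 in the upper 50% of regions and to 0.825 in regions within the top 2182 of both replicates, and turned to -0.0999 in the lower 50%, whose range of signal is narrow by construction. The X odds ratio was 0.937 with the nearest 5′ end. The lsy-2 ratio turned to 0.996 with 40 kb, and at 1.52 was no longer called against windows with as many regions.

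Lists called numbered 9 against circular shifts instead of 15. Against shifts the ratio of summits to chance turned for nuclear hormone receptors (1.45), collagens (1.42) and F-box and MATH genes (1.14), was no longer called for neuropeptides (0.567), ion channels (0.394), C-type lectins (0.34), hedgehog-related genes (0) and cytochrome P450 and UGT genes (0), and was newly called for bHLH (5.38) and histone genes (5.8); the shifts place few summits in promoters, which sets a lower expectation. With each replicate left out, heterochronic was at 3.53 to 5.38 and pan-neuronal at 3.14 to 6.29, and only the lower of each pair, without replicate 2 and without replicate 1, lost the call. Other odds ratios that lost their call are these. By construction, each 50% holds fewer summits, and members with a summit only in the other 50% count as having none. In the upper 50%: heterochronic 1.6, pan-neuronal 1.77 and hedgehog-related 0. In the lower 50%: synMuv B and DREAM 1.39, nuclear hormone receptor 0.346, ribosomal protein 1.89, collagen 0.407 and hedgehog-related 0. For those that follow the cause was not tested. With the narrower window: heterochronic 2.52; with the wider: hedgehog-related 0.243. With the nearest 5′ end: nuclear hormone receptor 0.708 and collagen 0.634. Among genes with 500 bp upstream: collagen 0.432 and hedgehog-related 0; among genes with a symbol: heterochronic 3.98. Newly called were Hox (9.56, nearest 5′ end) and homeobox (0.23, narrower window; 0.363, genes with a symbol). Of the list values under alternatives, 278 kept their side of the threshold and, for lists called, their direction. Another 22 lost the call, 5 gained it and 3 of called lists turned. Lists not called also changed sides of 1, such as body wall muscle (0.494 without replicate 1).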

Other observations

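A scan of 175 gene families by the letters of their symbols (at least 10 members each), chosen after the data were seen and adjusted over the families, called 20 with more and 20 with fewer summits than other genes. Outside the lists fixed in advance, translation initiation factor genes led by p-value: 15 of 25 eif genes had a summit (odds ratio 13.8, exact test, adjusted p = 5.57e-08), the strongest at eif-3.J (signal 667) and eif-3.I (616). The odds ratio was higher for Integrator genes (16.1). Genes of the mitochondrial ribosome were also called by exact test, with 17 of 41 mrpl genes (odds ratio 6.53, adjusted p = 3.19e-06; mrpl-28, signal 318) and 11 of 29 mrps genes (odds ratio 5.62, adjusted p = 0.000621). Of 26 nuclear pore genes, 13 had a summit (odds ratio 9.2, exact test, adjusted p = 6.02e-06), with npp-3 at signal 1222. Further families were also called. By exact test, these had a summit at 7 of 11 Integrator genes (ints; adjusted p = 0.000328), 6 of 11 RNA polymerase II subunit genes (rpb; adjusted p = 0.00237), 7 of 17 TFIID genes (taf, with taf-4 at signal 990; adjusted p = 0.00541) and 7 of 20 Mediator genes (mdt; adjusted p = 0.0136). None of the 10 general transcription factor genes (gtf) had one (exact test, adjusted p = 0.741). Called as well, by exact test, were the vacuolar ATPase family with a summit at 8 of 20 genes (vha; adjusted p = 0.0031) and the vacuolar sorting family with 9 of 31 (vps; adjusted p = 0.014). These genes were named after their values were seen.

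Tests of gene density, of the rank of ACCGTA outside ribosomal protein promoters, of lsy-2 against windows with as many regions, of other orders of the letters of ACCGTA and of ribosomal protein promoters without ACCGTA were chosen after the results they measure were partly seen; the others below were set before. The frequency of summits at ribosomal protein, proteasome and respiratory chain promoters was weighed first. Circular shifts did not reach the count for ribosomal protein genes: over 1000 shifts at most 7 had a summit, against 67 observed. The shifts put 21.1% of summits in promoter windows, against 64.7% observed, so a general preference for promoters raises lists above them. The test therefore cannot decide on gene density at ribosomal protein promoters. Signal there was not alike whatever the sequence, being 3.56 times higher at the 30 ribosomal protein promoters with ACCGTA by the summit than at the 37 without (permutation p = 0.00026), although this 6-mer was picked out in strong regions that include some of these promoters (it also ranked 1 in the 168 outside them) and the transcription of the promoters with and without it was not measured here. Recovery of strongly transcribed loci of any kind stays open, since summits were 20.6 times more frequent near tRNA genes than by chance. Another reason is that 70% of the 40 ribosomal protein genes with no ACCGTA in the promoter window still had a summit, against 8.45% of other such genes (Fisher's exact p = 2.41e-21). With ACCGTA in the window, 39 of 41 ribosomal protein genes and 12.3% of other genes had a summit. Recovery of strongly transcribed loci may add to the summits at ribosomal protein promoters. Binding of LSY-2 at promoters of strongly transcribed genes was not tested apart from such recovery, as no expression data or control ChIP was analysed here.

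ACCGTA near the strongest summits was weighed next. Base composition does not account for it, as no other order of its letters passed 21.5% of the 200 strongest regions, against 52.5% for ACCGTA. It was not a feature of ribosomal protein promoters alone, since 50% of the 168 strongest regions outside them had it (1.19% of their flanks), nor of 1 replicate, with 49% and 56% at the 200 strongest regions of replicates 1 and 2. The 168 regions are part of the 200 in which ACCGTA was picked, so their Fisher's exact p = 1.11e-42 is not an independent test. A candidate explanation is that ACCGTA is part of a sequence recognised at the strongest sites, by LSY-2 or by another protein bound there; these lists cannot separate the pair, and no biological explanation was tested. Around the 108 occurrences within 50 bp of these summits, T was the commonest base just before the 6-mer (57.4%) and C just after it (51.9%), with C at 65.7% at the position 3 bases after it.

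Signal of the listed regions at the lsy-2 locus lay at percentile 98.6 or above of random windows in both replicates, as predicted for extra copies of the transgene. It rests on 2 regions in replicate 1 and 1 in replicate 2, under a minimum of 5 that was set after these counts were seen, whereas the random windows held a median of 11, and against windows with as many regions the percentiles were 91.6 and 93.6. With 10 kb to each side replicate 2 was at percentile 95.6 and replicate 1 had no region, and with 40 kb the mean ratio was 0.996 and the percentiles were 96 in replicate 1 and 0.5 in replicate 2. Extra copies and chance cannot be told apart with so few regions. The signal is also relative to a control in a way that is not given, so extra copies need not raise it. The window held few regions: 6.4% of random 40 kb windows in replicate 1 and 1.6% in replicate 2 had as few.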
